A study of Mus musculus with 8 samples.

How the data were processed

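Expression was compared between 2 genotypes of C57BL/6 mice at postnatal day 7.5. Per the labels, the control animals were Runx2fl/fl and the mutant animals Gli1-CreERT2;Runx2fl/fl, with 4 libraries each, and tamoxifen was given into the peritoneum at postnatal day 3.5 at 1.5 mg per 10 g of body weight from a stock of 20 mg/ml in corn oil. RNA came from the apical part of the lower first molars and was isolated with a column kit for small samples, per the labels' protocols. The replicate numbers run from 2 to 5 in both groups, and the labels do not say whether a number marks a litter or a day, or whether each library is 1 animal. The p-values therefore measure the spread between these libraries, which may be in part technical.

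STAR 2.6.1d, Partek and the mouse build mm10 are named in the submitters' processing notes, without their roles. The gene annotation, counting settings, normalisation, low-expression filter and the model behind the p-values are not given in the sources used here. Per the file headers, the table is a gene-specific analysis of knockout against wild type, and the groups named there are called mutant and control here. It gives the authors' group means, which are normalised signal values on a linear scale and not read counts. The deposited total per gene equals 4 times the sum of both group means for all 17631 genes (relative tolerance 1e-06), so it is a normalised signal too. The deposited ratio is the mutant mean over the control mean for every gene. The signed fold change, a score without values between -1 and 1 per the file headers and values, restates that ratio. The p-value of each gene is the authors', and the deposited FDR, printed here as the adjusted p, equals the Benjamini-Hochberg adjustment of those p-values over the 17631 genes. The lowest means (0.0246 in the mutant, 0.0307 in the control) are each shared by 3 genes, so a fold near them is poorly defined.

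The table holds no values per library, so the analysis rests on the authors' comparison. A test on counts, which had been planned first, could not be used, and the second planned route was taken: the authors' adjusted p under 0.05, counted per direction. No standard error, spread between libraries, depth per library or count of libraries with a given direction can be stated. Log2 ratios were taken from the deposited ratio. Gene lists were tested with cameraPR in limma 3.58.1 (R 4.3.3), which compares the signed z of a list's genes, from the authors' p and direction, with that of all other genes. The preset correlation between genes was 0.01, with Benjamini-Hochberg adjustment over the 30 lists tested, and the RUNX family and sex-linked lists were described without a list test. An estimated correlation needs values per library and could not be had; with a preset of 0.05 all 5 list calls held. In simulated lists of 15 genes among the 17631, made by reassigning the real z values, 3.40% were called at an unadjusted p under 0.05 with no shift, 22.2% with a shift of 0.5 in z, 71.3% with 1 and 99.9% with 2 (1000 draws each). The simulated genes were drawn at random and vary independently. These rates therefore do not describe lists of genes that are regulated together, for which false calls can be more frequent.

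The genes named were chosen by a rule fixed before the data were examined. It took Runx2, Runx1, Runx3, Gli1 and Notum, then per direction the 10 genes past the threshold with the greatest fold among those whose higher mean reached the median of all genes (11.8), leaving out unnamed gene models, mitochondrial genes, pseudogenes and small RNAs, and then up to 3 measured members of each fixed list by p-value. A part of the rule that asked for libraries without overlap could not be applied. This gave 108 genes, of which 30 passed the threshold, and 2 genes that the rule takes are not reported here. Axin2, Dspp, Amelx, Ibsp, Col1a1, Ptch1, Hhip, Myh11, Kdm5d and Xist, members of fixed lists, were added after their values were seen.

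The 32 fixed lists cover the RUNX family, osteoblast, odontoblast, WNT, hedgehog, BMP and TGF-beta, FGF, periodontal ligament, dental mesenchyme, dental epithelium, ameloblast, osteoclast and its regulators, matrix, cell cycle, mitochondrial, stress, interferon and sex-linked genes, and markers of blood, vessel, nerve, muscle and cartilage cells. Some genes stand in more than 1 list. Gene symbols were matched to GENCODE M21 on GRCm38, the assembly that mm10 names, for 17562 genes (99.6%), which gave coordinates, gene type, GC content of transcripts and exonic length. The GC and length trend was taken over the protein-coding genes with a higher mean of at least 1. To subtract it, the signed z was fitted on GC content and log2 length with smooth terms (mgcv 1.9.3), which took 20.9% of its variance, and p-values and their adjustment were recomputed. This subtraction was checked on simulated data with a planted trend. It treats the whole trend as unwanted, so it also removes any real change that follows GC content or length. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Alternatives to the threshold, the filter, the list test and the scaling are in the closing section.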

Results

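RNA was sequenced from the apical part, which holds the growing root, of mouse lower first molars at postnatal day 7.5. The 2 groups had 4 libraries each. Control animals carried 2 floxed copies of Runx2, and mutant animals carried the same alleles together with Gli1-CreERT2, a tamoxifen-inducible recombinase expressed where Gli1 is active. Tamoxifen was given at postnatal day 3.5, per the labels, and the libraries were read as 2 x 50 nt on a NovaSeq instrument. The comparison asks which transcripts change in the developing root when Runx2, a transcription factor required for bone formation, is removed from Gli1-expressing progenitor cells, with the secreted WNT inhibitor Notum as a gene of interest. Only the mutant group carries the driver, so effects of the driver and of Runx2 loss cannot be told apart for any gene. The values are the authors' group means of normalised expression for 17631 genes, with their p-values. The depth of each library is unknown from these means, which sum to 955256 over genes in the mutant and 1050684 in the control. Unless stated otherwise, group means, fold sizes and adjusted p-values of single genes below come from the authors' deposited table, while log2 ratios and gene list tests were computed from it.

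Mutant molars had lower levels of bone-forming genes, of the contractile genes Acta2 and Tagln and of the WNT antagonist Sfrp2. Levels of the WNT antagonists Dkk2 and Sfrp4 and of cell division genes were higher. Pericyte and smooth muscle genes did not fall as a group, and WNT antagonists as a group did not pass in either direction. Runx2 itself was 1.62-fold lower, just outside the threshold. In the authors' deposited table, 139 of the 17631 genes passed an adjusted p of 0.05, of which 83 were higher and 56 were lower in the mutant. Of these, 23 were at least 2-fold higher and 19 at least 2-fold lower. Of the 32 gene lists fixed before the data were examined, 30 were tested as groups and 5 passed: cell cycle and mitochondrially encoded genes rose, and osteoblast, ameloblast and erythroid genes fell. The lowest adjusted p was 0.021, and 3401 genes had an unadjusted p under 0.05 where 882 would be so with no effect. When the trend of the ratios on transcript GC content and length, described below, was subtracted, 18 genes passed, 9 in each direction, and 12 of them were among the 139. That subtraction was chosen after the data were seen, and all 138 called genes with a GC value kept their direction under it. Kept direction is a weak check, because called genes differ by at least 0.31 in log2. The trend was mostly smaller, with median log2 ratios from 0.186 in the GC-poorest eighth of protein-coding genes to -0.120 in the GC-richest. Of the 30 called genes taken by the naming rule, 27 lost their call under the subtraction, all except Masp1, Prss12 and Krt75.

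The targeted gene, Runx2 (chromosome 17, 44495987 to 44814797, minus strand, GRCm38, protein-coding), had a mean of 65.1 in the mutant and 105.5 in the control in the authors' deposited table. This is 1.62-fold lower, with an unadjusted p of 0.000772 and an adjusted p of 0.0646, so that Runx2 lay just outside the threshold. The value covers the whole gene, including reads outside the floxed part, and the tissue holds cells without the recombinase. Osteoblast genes fell in the same comparison, as given below, and a difference in the tissue taken stays open for them. The Runx2 value alone therefore does not measure the deletion. The paralogs Runx1 (means 148.3 and 138.3, adjusted p = 0.577) and Runx3 (28.0 and 27.9, adjusted p = 0.958) and the shared partner Cbfb (log2 ratio 0.13, adjusted p = 0.588) did not pass. Among these 4 RUNX family genes, Runx2 was the 1 lower gene past the threshold when adjusted over the list alone. Gli1 itself (chromosome 10, 127329882 to 127341974), the locus of the recombinase, fell 1.95-fold from 38.8 to 19.9 (adjusted p = 0.0228). Notum (chromosome 11, 120653788 to 120661175) had means of 18.2 in the mutant and 34.9 in the control, which is 1.92-fold lower with an adjusted p of 0.0698, again outside the threshold.

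**Figure D1:**
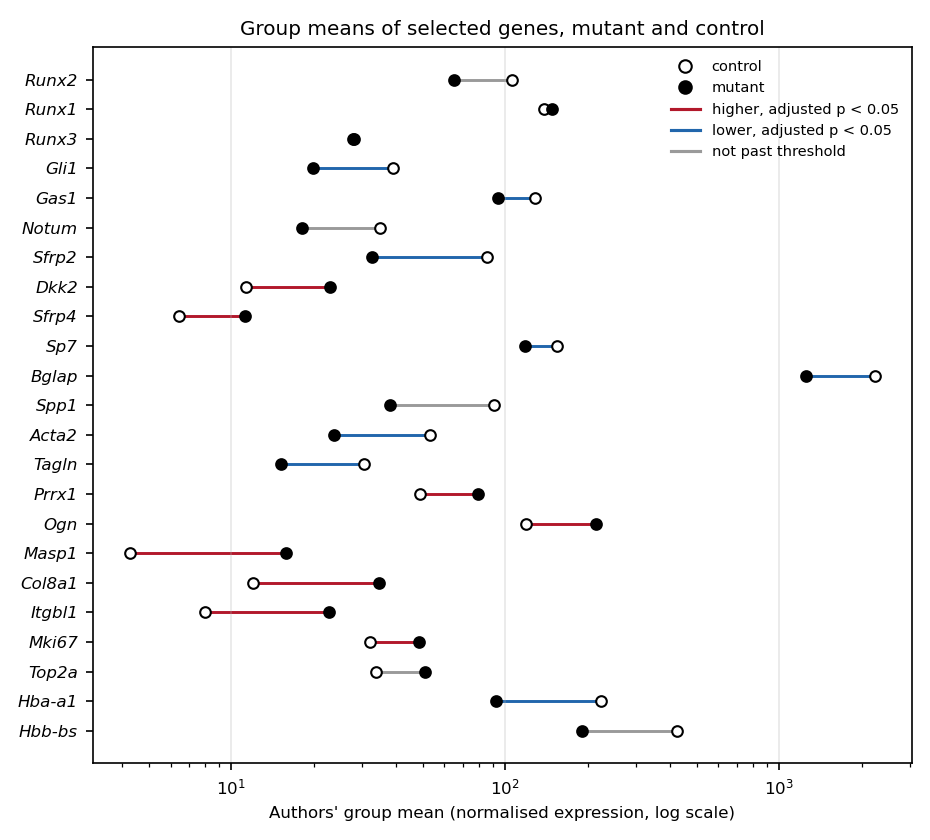
Group means from the authors' deposited table (normalised expression, log scale) for selected named genes, with open circles for the control and filled circles for the mutant, and no error bars because the table gives means alone. Coloured lines join the means of genes past an adjusted p of 0.05, and Runx2 (65.1 against 105.5) and Notum (18.2 against 34.9) are joined by grey lines.

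Among genes of at least median expression past the threshold, the 10 with the greatest rises included secreted and matrix proteins. Masp1, a complement-activating protease, rose 3.73-fold from 4.26 to 15.9 in the authors' deposited table (adjusted p = 0.0213). Col8a1, a short-chain collagen, rose 2.87-fold, Itgbl1, a secreted integrin beta-like protein, rose 2.84-fold, and Ogn, a small leucine-rich proteoglycan, rose 1.80-fold to a mean of 214.3. Dkk2 (2.03-fold), Prss12 (2.01-fold), the Y-linked Ddx3y (1.98-fold), the kinetochore gene Cenpf (1.77-fold), Itga4 (1.75-fold) and the keratin gene Krt75 (1.68-fold) made up the rest. On the lower side, the membrane dipeptidase gene Dpep1 fell from 14.3 to 4.07, and Sfrp2 fell 2.63-fold. The alpha-globin gene Hba-a1 fell 2.41-fold, Crispld2, which encodes a secreted protein, 2.33-fold, and the smooth muscle genes Acta2 and Tagln 2.23-fold and 2.01-fold. Gli1, Pacsin1 (1.92-fold), the guidance cue gene Ntn1 (1.83-fold) and Foxo6 (1.82-fold) completed the 10. Masp1, Prss12 and Krt75 were the 3 of these 20 that also passed after the GC and length trend was subtracted, with adjusted p-values of 0.0312, 0.0181 and 0.0258. Among those that lost their call, the log2 ratio went from 1.02 to 0.94 for Dkk2, from -1.40 to -1.33 for Sfrp2, from -1.16 to -1.14 for Acta2 and from -0.96 to -0.87 for Gli1, but from 0.85 to 0.45 for Ogn.

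Secreted WNT antagonists moved in both directions. Of 21 measured secreted and membrane WNT antagonists, 2 rose and 1 fell. Dkk2 rose from 11.3 to 22.9 (adjusted p = 0.0228) and Sfrp4 from 6.46 to 11.2 (adjusted p = 0.0318), while Sfrp2 fell from 85.9 to 32.6 (adjusted p = 0.0318) in the authors' deposited table. Dkk2 (0.94, adjusted p = 0.0523), Sfrp4 (0.68, adjusted p = 0.0847) and Sfrp2 (-1.33, adjusted p = 0.0824) kept log2 ratios near their first values under the GC and length subtraction but lost their calls. Adjusted over the list alone, 4 were higher and 3 lower, and the list as a group did not pass (median log2 ratio 0.03, mean -0.01, adjusted p = 0.715). None of the 15 WNT beta-catenin targets passed over all genes (list adjusted p = 0.630), and adjusted over the list alone 1 was higher and 1 lower. Their lowest p-values belonged to the stem cell receptor Lgr5 (2.84 against 0.912, adjusted p = 0.0670), to Notum, and to Tcf7 (47.7 against 65.9, adjusted p = 0.167). The feedback inhibitor Axin2 had 27.5 in the mutant and 29.8 in the control (adjusted p = 0.636). Of 37 WNT ligands and receptors, none passed over all genes (list adjusted p = 0.540), and 2 were higher and 3 lower adjusted over the list alone. Rspo1 had log2 ratio -0.90 (adjusted p = 0.0547) and Wnt3a -0.76 (adjusted p = 0.0677).

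In the hedgehog pathway, 2 of 15 genes fell, Gli1 and Gas1, a co-receptor whose mean was 94.5 in the mutant and 128.5 in the control (adjusted p = 0.0484), and both were lower adjusted over the list alone. The pathway targets Ptch1 (log2 ratio -0.16) and Hhip (0.22) did not pass, nor did the list (adjusted p = 0.114). Under the GC and length subtraction Gas1 went from -0.44 to -0.33 and lost its call (adjusted p = 0.187). Of 29 BMP and TGF-beta pathway genes none passed over all genes, while 2 were higher and 2 lower adjusted over the list alone (list adjusted p = 0.796). Bmpr2 stood at log2 ratio 0.33, Tgfb1 at -0.31 and Bmp4 at -0.44, with adjusted p-values in the authors' deposited table of 0.0882, 0.0904 and 0.0907, and the subtraction left Bmpr2 at 0.06. None of 18 FGF pathway genes passed over all genes, and 1 was lower adjusted over the list alone (list adjusted p = 0.917). Fgf1 had log2 ratio -0.35, Spred1 0.26 and Fgf2 0.38.

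Genes of osteoblasts and the mineralised matrix fell as a group (median log2 ratio -0.34, adjusted p = 0.000105), with all 19 measured members at a lower mean in the mutant. Of these, 2 passed over all genes and 4 adjusted over the list alone. Sp7, a transcription factor of osteoblast commitment downstream of Runx2, fell from 154.8 to 117.7 (adjusted p = 0.0447), and Bglap, which encodes osteocalcin, fell from 2234 to 1252 (adjusted p = 0.0484) in the authors' deposited table. Bglap has near-identical neighbouring copies, so its share of reads is uncertain. Among members that did not pass, Spp1 stood at 38.0 against 91.3 (adjusted p = 0.106) and Ibsp at 80.4 against 179.5 (adjusted p = 0.121). Col1a1 differed by log2 -0.02. The list still passed after the GC and length trend was subtracted (median -0.25, adjusted p = 0.000477), but Sp7 (log2 ratio -0.39 to -0.34, adjusted p = 0.132) and Bglap (-0.84 to -0.64, adjusted p = 0.208) lost their calls. In the same samples ameloblast genes and erythroid markers fell and the 10 skeletal muscle markers all had lower means, as given below.

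Of 10 odontoblast genes, 1 fell, Bglap, both over all genes and adjusted over the list alone, and the list did not pass (median -0.07, adjusted p = 0.114). Dspp, the main dentin matrix gene, had means of 7360 and 7714 (adjusted p = 0.931), Fam20c had log2 ratio -0.34 and Wnt10a -0.18. No osteoclast gene of 10 passed, over all genes or adjusted over the list alone (median -0.23, list adjusted p = 0.130), with Oscar at -0.93, Atp6v0d2 at -0.50 and Mmp9 at -0.57. Of 6 osteoclast regulators none passed over all genes, and 1 was lower adjusted over the list alone (list adjusted p = 0.0723). Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, had the low means of 0.178 and 0.590 (adjusted p = 0.0825), and its decoy receptor gene Tnfrsf11b had log2 ratio -0.27 and Pthlh -0.25.

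**Figure D2:**
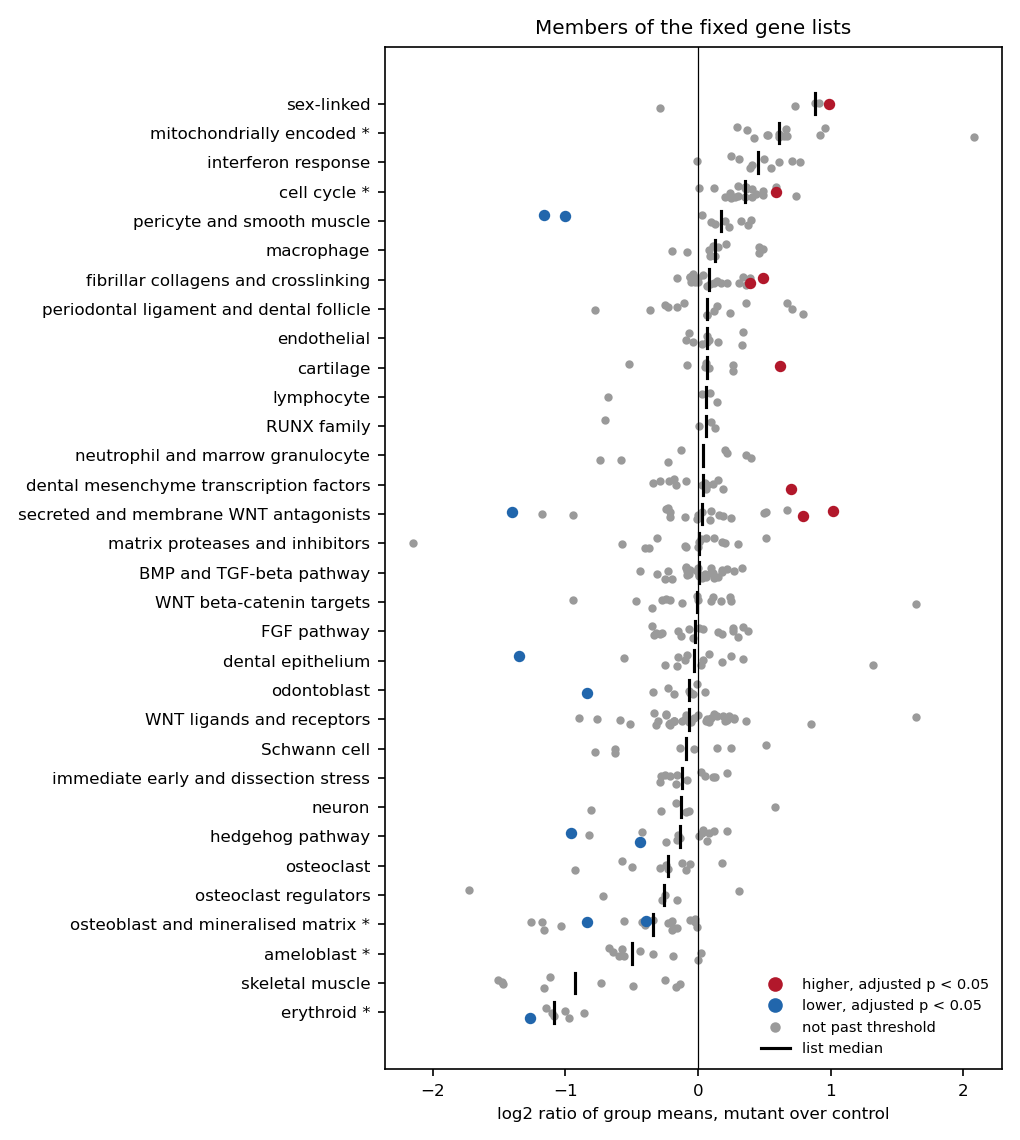
Log2 ratio of group means, mutant over control (horizontal axis), for each measured member of the 32 fixed gene lists (vertical axis), with red and blue points for genes past an adjusted p of 0.05, grey for the others, and black bars for list medians. Stars mark the 5 lists past an adjusted p of 0.05, whose medians run from -1.09 for erythroid to 0.61 for mitochondrially encoded genes.

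Connective tissue genes gave single rises. Prrx1, a mesenchymal transcription factor, rose 1.62-fold to 79.4 (adjusted p = 0.0474) and was the 1 of 14 dental mesenchyme transcription factors to pass over all genes. The GC and length subtraction ended its call (log2 ratio 0.70 to 0.52, adjusted p = 0.249) and took the log2 ratio of Postn from 0.71 to 0.25 (adjusted p = 0.455). Adjusted over the list alone, 1 was higher and 1 lower, and the list did not pass (adjusted p = 0.630). Dlx2 had log2 ratio -0.29 and Pitx1 -0.34. None of 15 periodontal ligament and dental follicle genes passed over all genes (list adjusted p = 0.518), but 4 were higher and 1 lower adjusted over the list alone. The follicle protein gene Postn had means of 326.7 and 200.2 (adjusted p = 0.0590), Mkx 17.0 and 10.7 (adjusted p = 0.0888), and Spon1 48.0 and 82.3 (adjusted p = 0.0608) in the authors' deposited table. Of 22 fibrillar collagen and crosslinking genes, 2 rose over all genes and adjusted over the list alone. These were Col14a1 (1.31-fold, adjusted p = 0.0418) and Col6a3 (1.41-fold, adjusted p = 0.0438), and Col12a1 had log2 ratio 0.36. Both lost their calls under the subtraction, at log2 ratios of 0.36 and 0.49 (adjusted p = 0.0912 and 0.0902). That list lay just outside the threshold (adjusted p = 0.0534) and passed after the GC and length trend was subtracted (adjusted p = 0.0143), but not with that subtraction and a preset correlation of 0.05 (adjusted p = 0.103). None of 16 matrix proteases and inhibitors passed over all genes (list adjusted p = 0.540), and 2 were lower adjusted over the list alone. The collagenase gene Mmp13 stood at 15.1 against 67.1 (adjusted p = 0.0808), Timp1 at log2 ratio -0.40 and Adamts2 at -0.37. Hapln1, which links hyaluronan to proteoglycans, rose 1.54-fold (adjusted p = 0.0392) as 1 of 8 cartilage genes, also adjusted over the list alone (list adjusted p = 0.248), with Col9a1 at 0.26 and Comp at -0.52. The GC and length subtraction took Hapln1 from a log2 ratio of 0.62 to 0.36 and ended its call (adjusted p = 0.239).

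Ameloblast genes, among them genes of enamel matrix and its proteases, fell as a group (median log2 ratio -0.50, adjusted p = 0.00685). Of the 10 members 8 had lower means in the mutant. The protease gene Mmp20 (532.5 in the mutant and 531 in the control) and Wdr72 (13.7 and 13.5) did not fall. None of the 10 passed over all genes, and 2 were lower adjusted over the list alone. Klk4 had means of 320.6 and 510.8 (adjusted p = 0.0697), Amtn 1132 and 1664 (adjusted p = 0.181) and Fam83h log2 ratio -0.34 in the authors' deposited table. Amelx, the most abundant, took 11.7% of the summed means in the mutant and 16.7% in the control (log2 ratio -0.64, adjusted p = 0.457). The list passed after the GC and length trend was subtracted (median -0.51, adjusted p = 0.00133). Erythroid and osteoblast genes fell in the same comparison (medians -1.09 and -0.34), and skeletal muscle markers had lower means (median -0.93). Of 14 dental epithelium genes, Krt18 fell from 4.58 to 1.80 (adjusted p = 0.0484), and adjusted over the list alone 1 was higher and 1 lower (list adjusted p = 0.950). The subtraction left Krt18 at log2 ratio -1.22 without its call (adjusted p = 0.194). Krt15 had means of 15.8 and 6.34 (adjusted p = 0.0545, and 0.0383 after the GC and length trend was subtracted) and Trp63 log2 ratio 0.25.

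Cell cycle genes rose as a group (median log2 ratio 0.35, adjusted p = 6.43e-10), and all 21 measured members had higher means in the mutant. Mki67, a marker of dividing cells, rose 1.51-fold from 32.2 to 48.6 (adjusted p = 0.0486), and was the 1 member past the threshold over all genes. Adjusted over the list alone 12 were higher. Top2a had means of 51.0 and 33.9 (adjusted p = 0.0608) and Mcm6 42.2 and 33.2 (adjusted p = 0.0715) in the authors' deposited table. The list passed after the GC and length trend was subtracted (median 0.30, adjusted p = 4.38e-12), but Mki67 lost its call (log2 ratio 0.59 to 0.48, adjusted p = 0.197).

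Erythroid markers fell as a group (median log2 ratio -1.09, adjusted p = 6.52e-06), with 7 of 7 lower adjusted over the list alone and 1, Hba-a1, over all genes. The beta-globin gene Hbb-bs had means of 189.9 in the mutant and 422.7 in the control (adjusted p = 0.0700) and the haem synthesis gene Alas2 5.93 and 11.6 (adjusted p = 0.0774) in the authors' deposited table. Hba-a1 and Hba-a2 share reads, so their split is uncertain. The list passed after the GC and length trend was subtracted (median -0.91, adjusted p = 3.50e-05), but Hba-a1 lost its call (log2 ratio -1.27 to -1.09, adjusted p = 0.216). The 10 skeletal muscle markers all had lower means (median -0.93), but none passed over all genes or adjusted over the list alone, and the list lay just outside the threshold (adjusted p = 0.0534). They were scarce, with Myl1 at 0.395 against 1.10, Ckm at 0.181 against 0.501 and Acta1 at 0.889 against 1.98. Among 10 pericyte and smooth muscle genes, the contractile genes Acta2 (23.7 against 53.0, adjusted p = 0.0318) and Tagln (15.2 against 30.4, adjusted p = 0.0418) fell. The other 8 members had higher means, and the list median was 0.17. The smooth muscle myosin gene Myh11 had 4.53 in the mutant and 4.44 in the control (adjusted p = 0.934). Adjusted over the list alone, 2 were higher and 2 lower, and the pericyte marker Cspg4 had log2 ratio 0.32 (list adjusted p = 0.648).

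Markers of endothelial, immune and nerve cells and genes of the interferon and stress responses held no gene past the threshold over all genes. The 10 endothelial genes (Kdr 0.34, Tek 0.33 and Cdh5 0.15 on the log2 scale) had a list adjusted p of 0.540 and none passed adjusted over the list alone. Of 11 macrophage genes 1 was higher adjusted over the list alone, with Mrc1 at 0.46, Aif1 at 0.49 and Adgre1 at 0.46. Their list adjusted p was 0.114, 0.00814 after the GC and length trend was subtracted, and 0.0364 after it with a preset correlation of 0.05. The 8 granulocyte genes (Lcn2 0.40, S100a8 0.36, Retnlg -0.74) and 4 lymphocyte genes (Cd4 0.14, Cd79b 0.09, Cd79a -0.68) gave list adjusted p-values of 0.950 and 0.989, with none past adjusted over the list alone. Of 10 interferon response genes none passed adjusted over the list alone (list adjusted p = 0.0534, 0.0435 after the subtraction, and 0.107 after it with a preset correlation of 0.05), with Oasl2 at 0.71 and Isg15 at 0.77. The 8 Schwann cell genes (Mbp -0.63, S100b -0.63, Cdh19 0.51) gave 0.566 with none past adjusted over the list alone. Of 6 neuron genes (list adjusted p = 0.630) 1 was higher and 1 lower adjusted over the list alone, Gap43 (0.58) and Stmn2 (-0.81), while Tubb3 had -0.28. Stmn2 passed after the subtraction (adjusted p = 0.0258). Of 12 immediate early and dissection stress genes 1 was lower adjusted over the list alone (list adjusted p = 0.248), with Zfp36 at -0.28, Jun at -0.25 and Junb at -0.29.

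Mitochondrially encoded genes rose as a group (median log2 ratio 0.61, adjusted p = 7.20e-06). All 13 had higher means, none passed over all genes, and 8 were higher adjusted over the list alone. In the authors' deposited table mt-Atp8 had 691.9 in the mutant and 164.1 in the control (adjusted p = 0.102), mt-Atp6 3294 and 1692, and mt-Nd3 247.7 and 130.8. These transcripts are GC-poor (median 37.1%), and after the GC and length trend was subtracted the median was 0.27 (adjusted p = 0.0101, and 0.0490 with a preset correlation of 0.05). Of the 5 sex-linked genes, which were described and not tested as a list, the Y-linked Ddx3y rose from 12.9 to 25.6 (adjusted p = 0.0486). These genes are GC-poor (median 36.4%), and after the GC and length trend was subtracted the log2 ratio of Ddx3y went from 0.99 to 0.54 (adjusted p = 0.356). The sex of the animals is not given in the sources used here. Adjusted over the list alone 4 were higher, Ddx3y, Eif2s3y (12.7 against 7.66), Uty (8.58 against 4.67) and Kdm5d (7.74 against 4.14), while Xist, expressed from the inactive X chromosome, had a log2 ratio of -0.29 (adjusted p = 0.457).

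The ratios followed the composition of the transcripts. Over 13128 protein-coding genes the log2 ratio had a Spearman rho across genes of -0.43 with GC content and 0.28 with exonic length. Genes are not independent replicates, so no p-value is given. In the GC-poorest eighth of genes 33.1% were higher and 1.16% lower in the mutant at an unadjusted p under 0.05, and in the GC-richest eighth 2.13% were higher and 24.1% lower. Genes called higher had a median GC content of 42.6% and a median length of 6677 nt, and genes called lower 55.6% and 2891 nt, against 49.9% and 3893 nt over all genes. A scaling that equalises the summed means of the groups would raise every log2 ratio by 0.137; called genes differ by at least 0.31, so their signs do not depend on it. List medians from -0.13 up to 0 would change sign under it.

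**Figure D3:**
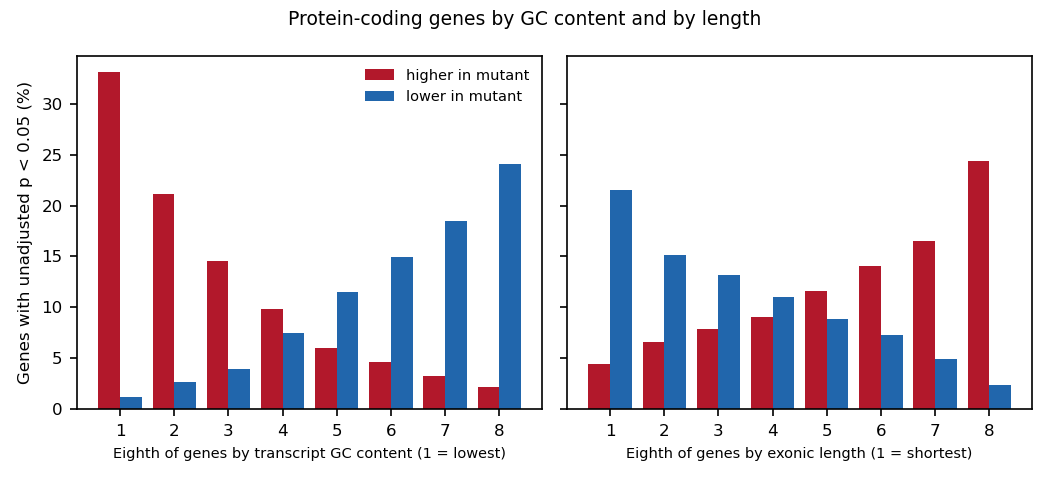
Percentage of protein-coding genes with an unadjusted p under 0.05 that were higher (red) or lower (blue) in the mutant, in eighths of genes ordered by transcript GC content (left) and by exonic length (right). The share of higher genes goes from 33.1% in the GC-poorest to 2.13% in the GC-richest eighth, and from 4.39% in the shortest to 24.4% in the longest eighth.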

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

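No paired analysis was possible because the file holds group means and no values per library. For the same reason, leaving out replicates, other normalisations, other test tools, pseudocounts, an estimated correlation and the rotation test fry were not run. Depth per library is unknown, so its limits were not assessed. Subtracting the GC and length trend, equalising the summed means and leaving out chromosome Y, haemoglobin and mitochondrial genes were chosen after the data were seen.

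Of the 139 genes (83 higher, 56 lower), 42 (23 and 19) were also at least 2-fold different. An adjusted p under 0.10 gave 641 (354 and 287) and an unadjusted p under 0.05 gave 3401 (1744 and 1657), while the authors' adjusted p under 0.01 gave 0 (0 and 0). These follow from the thresholds. A minimum of 1 or of the median on the higher mean gave 168 and 141 genes, and let 5 more named genes past in the first case, and leaving out the 28 Y-linked, haemoglobin and mitochondrial genes gave 137. After the GC and length subtraction 18 genes passed (9 and 9). Among the 30 genes past the threshold that the naming rule took, 30 kept their direction and 3 still passed. The kept direction is a weak check, as described above. The fit lowers the ratio of GC-poor long genes and raises that of GC-rich short ones, the sides on which the called genes lie.

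Runx2 kept its log2 ratio of -0.70 and passed with the median filter (adjusted p = 0.0488), because fewer genes were tested. Its adjusted p was 0.0531 with the minimum of 1, and 0.0803 after the subtraction (-0.73). Notum stayed outside the threshold, with adjusted p-values from 0.0533 to 0.253 and log2 ratios from -0.94 to -0.80. Equal summed means gave Runx2 -0.56.

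The number of lists past the threshold was 5 with the preset correlation of 0.05, without genes shared between lists and with the minimum of 1, 6 with the median filter and 7 with ranks. It was 8 with the log2 ratio as statistic and 8 after the subtraction, where macrophage, fibrillar collagen and interferon lists joined, and 6 with both the subtraction and the correlation of 0.05, where the collagen and interferon lists dropped out again. Some weak results changed sign, none of them past the threshold; the cause was not tested. The subtraction gave Runx1 -0.03 and Cbfb -0.02 in log2. It moved the mean z of dental mesenchyme transcription factors from -0.26 to 0.08, and of dental epithelium from -0.01 to 0.22, at either correlation. Without shared genes dental epithelium stood at 0.04, and with the median filter at 0.47. On the log2 scale the mean was -0.01 for WNT antagonists, 0.00 for dental mesenchyme transcription factors, -0.06 for granulocyte, -0.10 for lymphocyte and -0.04 for pericyte and smooth muscle genes, each opposite in sign to the mean z or, for the dental mesenchyme genes, near 0. List medians were above 0 where the mean z was below it for dental mesenchyme (0.04), BMP and TGF-beta (0.01) and matrix protease genes (0.01).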

Other observations

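The lists of ribosomal protein, respiratory chain, mitotic and axon guidance genes, the tests of the Gli1 and mineralised tissue patterns, and the genes named with these lists were chosen after the data were seen. The p-values of these lists are therefore descriptive and are no independent evidence. The 86 cytosolic ribosomal protein genes fell as a group (median log2 ratio -0.24, adjusted p over these 4 lists 1.07e-23, and 5.85e-09 with a preset correlation of 0.05): 82 had lower means in the mutant, 54 were lower adjusted over the list alone, and none passed over all genes. Rps16, for example, had means of 530.1 and 692.7 in the authors' deposited table. Fau, a ribosomal protein gene outside this list, did pass over all genes (293.4 in the mutant and 398.2 in the control, adjusted p = 0.0391). The 94 nuclear-encoded respiratory chain genes fell relative to other genes (median -0.13, adjusted p = 5.86e-09, and 0.000686 with a preset correlation of 0.05), although equal summed means would put their median at 0.01. This was opposite to the 13 mitochondrially encoded genes, which rose. The respiratory chain list was taken by symbol pattern and is not purely one of complex subunits. It also holds assembly factors, such as Ndufaf1 and Ndufaf4, and scarce entries such as Cox6c2 (0.129 in the mutant and 0.291 in the control). The ribosomal and respiratory chain falls held after the GC and length subtraction (medians -0.19 and -0.08, adjusted p = 2.00e-21 and 7.90e-07).

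A list of 76 genes, taken by symbol pattern for mitotic chromosome and spindle proteins, rose as a group (median 0.23, adjusted p = 8.50e-09). With a preset correlation of 0.05 its adjusted p was 0.000686. The pattern also took in kinesins with other roles, such as Kif1a, Kif5b and Kif19a, and Kif1bp, which is not a kinesin. The list is therefore not a purely mitotic set. Over all genes 6 members passed the threshold, among them the condensin genes Smc2 (1.56-fold) and Smc4 (1.43-fold), Cenpf and the spindle gene Aspm (1.59-fold). After the GC and length subtraction the list median was 0.16 (adjusted p = 2.36e-06), but none of Smc2, Smc4, Cenpf and Aspm passed. Of 52 axon guidance ligands and receptors, 5 rose in the authors' deposited table: the receptors Epha4 (1.48-fold), Epha7 (1.52-fold) and Ephb2 (1.47-fold) and the secreted cues Sema3c (1.94-fold) and Slit2 (1.39-fold). Ntn1 fell 1.83-fold. After the GC and length subtraction none of Epha4, Epha7, Ephb2, Sema3c, Slit2 and Ntn1 passed. The receptor Epha3 passed only after the subtraction (adjusted p = 0.0955 before and 0.0383 after). It was lower in the mutant, with log2 ratios of -0.60 before and -0.80 after. The list passed at the preset correlation of 0.01 (adjusted p = 0.0306, and 0.0259 after the subtraction). It lost its call at 0.05 (adjusted p = 0.158 without the subtraction).

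The ratios of the whole transcriptome followed GC content and length. The trend was present outside a few gene families: without 353 ribosomal, respiratory, mitotic, cell cycle and mitochondrial genes the Spearman rho with GC content was -0.43, as over all 13128. Leaving out so few genes could hardly have moved rho, so the unchanged value is no further test. A candidate explanation is a sequence-dependent difference between the libraries of the groups, such as RNA quality or amplification, which would act on noncoding transcripts too. Over 472 noncoding genes rho was -0.35 (-0.43 to -0.26 in the central 95% of resamplings of these genes, which are not independent replicates), as this explanation requires. Since every mutant library is compared with every control library and preparation batches are not given in the sources used here, a shift in cell makeup or RNA turnover with genotype stays open and was not tested.

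Gli1 stood at 0.514 of its control level. Lower hedgehog signalling stays open: the pathway targets Ptch1 and Hhip had log2 ratios of -0.16 and 0.22, neither past the threshold, and no test of the targets as a set is reported. The driver allele is another candidate explanation: if the recombinase insertion disrupts 1 Gli1 copy, a ratio near 0.5 follows with or without Runx2. Because the control group carries no driver, this cannot be told apart from an effect of Runx2 loss on Gli1. The same limit holds for every other gene in the comparison.

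Osteoblast, ameloblast and erythroid genes fell, and skeletal muscle markers had lower means, in the same comparison. This might come from differences in the tissue taken with each sample. For the lists other than ameloblasts, which belong to the tooth, that could be tissue around the tooth. Less whole blood or marrow would lower granulocyte genes with the erythroid ones. The median log2 ratio of 8 granulocyte genes lay 1.13 above that of 7 erythroid genes. The standard error over genes, which belongs to the difference of the list means, was 0.16. The granulocyte genes were scarce, at means of 0.361 to 5.28 in the mutant, and genes of a list are not independent. These values therefore do not decide whether the mutant samples held less blood. Less adhering bone would lower osteoclast markers too. Their median was -0.23 (standard error of their mean over genes 0.10). This leaves the explanation open, since Runx2 loss in bone-forming cells could do the same. Of the 19 osteoblast genes, 8 stand in another fixed list, and odontoblasts of the tooth also express several. Fewer red cells without fewer granulocytes, or a lower output of bone-forming cells in the root region, also stay open and were not tested. The cause of the ameloblast fall was not tested either.

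Y-linked genes had higher means in the mutant, from 1.66-fold for Eif2s3y to 1.98-fold for Ddx3y in the authors' deposited table, and log2 ratios of 0.31 and 0.54 for these genes after the GC and length subtraction, neither past the threshold. The sex of the animals is not given in the sources used here. Whether the groups were matched for sex is therefore unknown, and effects of sex on other genes were not tested. The 613 genes of chromosome X had a median log2 ratio of 0.10, and of 0.01 after the subtraction.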
